A study of Homo sapiens with 36 samples.

How the data were processed

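RNA of BxPC-3 cells treated with 1 of 5 compounds at 3 µM or with DMSO for 2 or 4 h was measured by polyA-selected, paired-end RNA sequencing with 150-base reads on an Illumina NovaSeq, per the submitters' processing notes. The same notes say that the authors quantified gene levels against hg38 with Salmon 1.10.3, run through version 3.18.0 of nf-core/rnaseq. The annotation release is not given in the sources used here. The deposited gene table holds Salmon estimated counts, which are not whole numbers and are not normalized for depth, and the deposited length-scaled table holds estimated counts rescaled for transcript length. Scaled counts, gene TPM and transcript-level tables were not used here. The table has 29744 genes, 61 duplicated gene names and no mitochondrially encoded genes. All 36 columns were matched to a compound, a time and a replicate number by their names, and no library was left out of the fits reported as results.

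Estimated counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and the 12 groups as design, which left 14988. Libraries were scaled by TMM, and a negative binomial model with 1 mean per compound and time was fitted to all 36 libraries with robust quasi-likelihood dispersions (glmQLFit, glmQLFTest); the common biological coefficient of variation was 0.135. Benjamini-Hochberg adjustment was applied within each comparison, with calls at an adjusted p under 0.05. Each compound was compared with DMSO at its time, TRAP1 with each of the other 4 compounds, and JQ1 with TRAP-1-NegP, 20 comparisons in all. Further contrasts tested the difference of each effect between 4 and 2 h, DMSO at 4 against 2 h, and the departure of TRAP1 from the sum of the TRAP-1-NegB and TRAP-1-NegP effects. All tests are two-sided. Totals ran from 15288688 to 26608325 estimated counts per library. The SE given with a value holds counting error and the spread between replicates together, which were not separated.

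The comparisons, the named-gene rule, 24 gene lists, the tests and most alternatives were chosen before the data were examined. The rule named, by size of change among genes with an adjusted p under 0.05, a mean of at least 5 CPM over the 6 libraries and all 3 libraries of 1 group above all 3 of the other, the top 10 rises and falls of TRAP1 against DMSO, the top 5 of each other comparison, and the top 3 of JQ1 against TRAP-1-NegP. It also named up to 4 members of a list per direction by adjusted p, and a panel of 12 genes (CDKN1A, MDM2, BBC3, GDF15, FAS, BTG2, MYC, HEXIM1, SERPINI1, BRD2 and 2 more). The lists covered p53 targets and their arrest, apoptosis and DNA repair branches, G2/M genes, G1/S genes, MYC and ribosome biogenesis, BET inhibitor-induced genes, BET proteins and pause release, immediate early genes, NF-kB, BCL2-family, the integrated stress response, the unfolded protein and heat shock response, NRF2, cholesterol and fatty acid synthesis, type I interferon, hypoxia and glycolysis, TGF-beta and YAP, pancreatic ductal and epithelial genes, and markers of mesenchymal and of haematopoietic and endothelial cells. The list of mitochondrially encoded genes had no measured member, so 23 lists were tested, with camera (limma 3.58.1) at a preset correlation of 0.01, and also with an estimated correlation. List p-values were adjusted over the 23 lists of a comparison. The results of 1 of these lists and of some single genes are not reported here.

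Shared responses were set beside 10 simulations of libraries without compound effects that shared their controls. Gene positions, GC content and transcript length came from GENCODE v29 on GRCh38, a release chosen here; 13470 of the tested genes, 89.9%, had a GC content and length.

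Alternatives changed 1 choice at a time: DESeq2 size factors within edgeR, the DESeq2 1.42.0 Wald test, no count filter, a stricter filter (a mean of at least 1 CPM in 1 group and 10 counts in 3 libraries), length-scaled counts, a replicate block, a fit of only the groups compared, each library left out in turn, and an estimated list correlation. A pair of alternatives was added after the data were seen: leaving out both libraries that stood apart, and a loess correction of counts for GC content and length. Other splits of the libraries refitted only the groups compared. Tested on simulated data with 200 changed genes of the TRAP1 comparison at 4 h, the edgeR procedure recovered 77% of genes changed 1.5-fold and 100% of those changed 3-fold, with 4 calls outside. The real comparison called 7000 genes, far more than were changed in the simulation. The simulation therefore does not test the scaling, or the number of false calls, under so broad a response. An added GC trend raised the calls outside to 3973, and the correction returned them to 4 but lowered recovery of genes changed 1.5-fold from 74% to 66%. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.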

Results

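BxPC-3, an established human pancreatic adenocarcinoma cell line, was exposed to 3 µM of TRAP1, TRAP-1-NegB, TRAP-1-NegP, JQ1 or MS78, or to DMSO, for 2 or 4 h, and polyadenylated RNA was sequenced. The name TRAP1 stands here for the compound, not for the gene of that symbol. JQ1 is an inhibitor of the BET bromodomain proteins, the family that includes BRD2. The series record calls the other compounds controls of TRAP1, and it asks how transcript levels respond. The labels do not state what the suffixes NegB and NegP stand for. The 12 groups held 3 libraries each, 36 in all. Total estimated counts per library ran from 15288688 (TRAP-1-NegB, 2 h, replicate 1) to 26608325 (MS78, 2 h, replicate 1). Of 29744 genes in the table, 14988 passed the count filter and were tested. Every level below is a mean of counts scaled to library totals adjusted by their TMM factors (CPM) ± SD with n = 3. Every change is a log2 fold change, and the error given with a change is its SE. The labels number the replicates but do not say whether they were separate cultures, so the replicate error may be technical only.

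TRAP1, TRAP-1-NegP and JQ1 libraries lay apart from the others and separated by time. The first principal component of the 2000 most variable genes, 21.3% of their variance, held DMSO, TRAP-1-NegB and MS78 libraries of both times between −26.7 and −20.3, the TRAP-1-NegP, TRAP1 and JQ1 libraries of 2 h between 5.48 and 13.3, and those of 4 h between 26.7 and 43.9. A pair of libraries stood apart from their groups. TRAP1 replicate 1 at 4 h lay at −60.7 on the second component, against −16.1 and −0.28 for the other TRAP1 libraries of that time, and had 1287 tested genes at a count of 0, against 929 and 503. MS78 replicate 1 at 2 h differed from replicates 2 and 3 of its group by a chi-square per degree of freedom of 27.1 and 43.8, against 7.05 between those replicates and 4.51 to 15.1 for the pairs of the other groups.

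**Figure D1:**
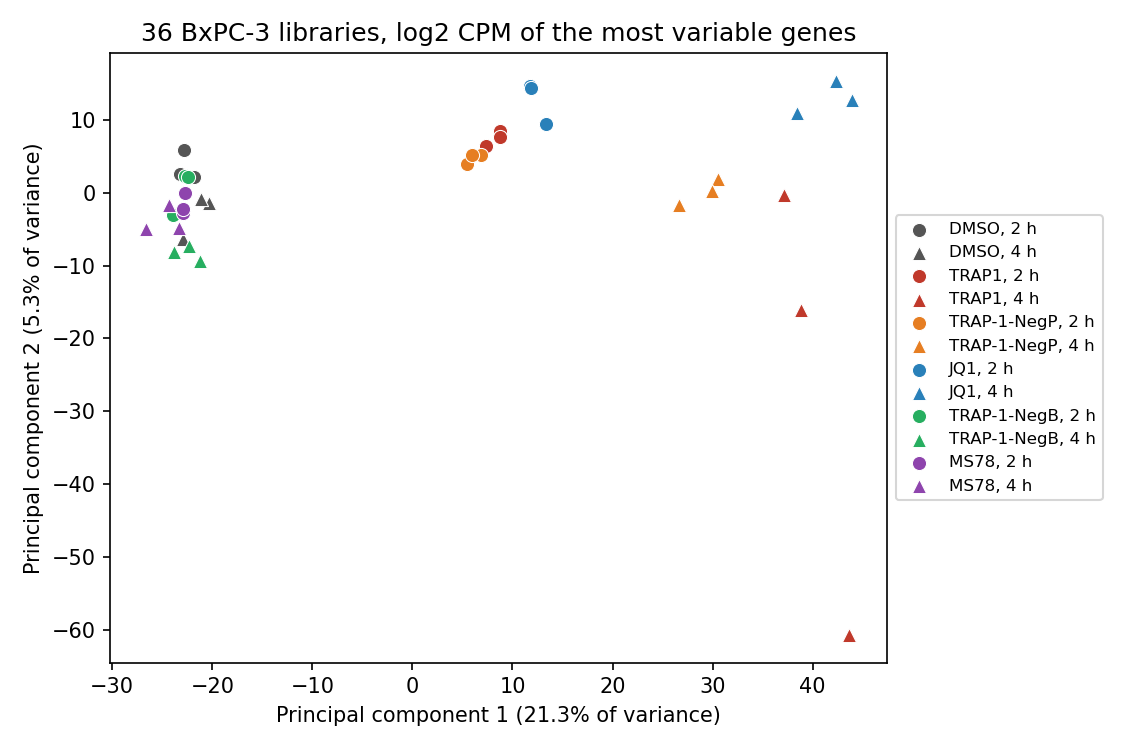
Principal components 1 and 2 (arbitrary units, percent of variance on the axes) of log2 CPM of the 2000 most variable tested genes; each point is 1 of 36 libraries, coloured by compound and shaped by time. DMSO, TRAP-1-NegB and MS78 libraries lie together at the left, and TRAP1 replicate 1 at 4 h lies at −60.7 on the second component.

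The genes that recur in the comparisons below lie, in build GRCh38, at chromosome 6, 36676460 to 36687339 (CDKN1A), chromosome 8, 94925972 to 94949411 (TP53INP1), chromosome 19, 18374731 to 18389176 (GDF15), chromosome 12, 68808176 to 68850686 (MDM2), chromosome 17, 45148502 to 45152101 (HEXIM1), chromosome 8, 121612116 to 121641390 (HAS2), chromosome 7, 155297776 to 155310235 (INSIG1), chromosome 15, 74719542 to 74725610 (CYP1A1) and chromosome 2, 38066973 to 38109902 (CYP1B1). All 9 are annotated as protein-coding. Counts in square brackets after a gene list are those adjusted over the list alone. Each gene named for the size of its change had all 3 libraries of 1 group above all 3 of the other, an arrangement that chance gives in 10% of genes.

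TRAP1 against DMSO at 2 h shows which transcripts moved early under the compound that the series is named for. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21 and is a classical p53 target, stood at 2046 ± 30.4 CPM with TRAP1 and at 162 ± 7.93 CPM with DMSO, a rise of 3.66 ± 0.053 (adjusted p = 3.2e-49). TP53INP1, a stress protein gene induced by p53, rose by 2.82 ± 0.31 (adjusted p = 7.8e-10), from 2.12 to 15 CPM. The other 8 genes with the largest rises were FAM46C (2.81), POU3F1 (2.66), VASN (2.62), RGS16 (2.51), TNFSF9 (2.45), BAMBI (2.40), EGR1 (2.31) and OSR2 (2.25). Among them EGR1 is an immediate early transcription factor and TNFSF9 the ligand of the T-cell receptor 4-1BB. HAS2, which makes hyaluronan, was 13.1-fold lower, a change of −3.71 ± 0.26 (adjusted p = 3.7e-12), from 53 ± 1.44 to 4.01 ± 1.24 CPM. The next largest falls were ALKBH4 (−2.74), DOK7 (−2.30), PRICKLE1 (−2.05), HCAR1 (−1.99), JRK (−1.93), LDOC1L (−1.90), RGS4 (−1.87), TIGD5 (−1.86) and ZNF689 (−1.82).

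Among p53 target genes at 2 h of TRAP1, 40 of 82 rose and 9 fell, or 42 and 12 when adjusted over the list alone (median 0.27, adjusted p = 8.6e-18). The cell-cycle arrest branch moved as a block: 12 rises and 0 falls among 13 [12 and 0] (median 1.34, adjusted p = 4.9e-51), including PLK3 (1.81), BTG2 (2.07) and SESN2 (1.63). Of the apoptosis branch, 8 of 17 rose and 3 fell [9 and 4] (median 0.24, adjusted p = 0.0056), with TNFRSF10D (1.37), PMAIP1 (1.29) and TP53I3 (0.94) up and the nuclease gene AEN down (−1.48). In the DNA repair branch, 4 of 7 rose and 0 fell [5 and 0] (median 0.63, adjusted p = 1.7e-05), led by the translesion polymerase gene POLH (2.03). GDF15, a secreted stress cytokine, rose by 2.19 ± 0.15 (adjusted p = 6.9e-15) and the proapoptotic BBC3 by 1.73 ± 0.33 (adjusted p = 2.6e-05). MDM2, which encodes a ubiquitin ligase, stood at 0.05 ± 0.12 (adjusted p = 0.82). BET inhibitor-induced genes rose as well, with 14 rises and 0 falls among 17 [14 and 0] (median 1.05, adjusted p = 5.4e-30). BRD2 stood at 1.09, SERPINI1 at 2.59 and HEXIM1, the inhibitor of the elongation factor P-TEFb, at 1.23.

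Stress programmes followed the same direction at 2 h. Of unfolded protein and heat shock genes, 19 of 25 rose and 1 fell [20 and 1] (median 0.48, adjusted p = 2.4e-28), with the chaperone genes HSPA1B (1.39), HSPA5 (0.97) and DNAJB1 (0.87). Immediate early genes shifted up, with 19 rises and 6 falls among 33 [20 and 7] (median 0.66, adjusted p = 1.8e-06). Integrated stress response genes did too, with 15 rises and 3 falls among 23 [16 and 3] (median 0.38, adjusted p = 1.2e-06). In them, ATF3 rose (2.02) and TRIB3 fell (−1.43). Cholesterol and fatty acid synthesis genes gave 13 rises and 0 falls among 25 [14 and 0] (median 0.28, adjusted p = 1.7e-06), led by INSIG1 at 1.75. In the NF-kB list, 0 of 27 rose and 8 fell [0 and 8] (median −0.17, adjusted p = 0.060, and adjusted p = 0.045 with an estimated correlation). The falls included BCL3 (−1.08) and the chemokine gene CXCL1 (−1.97). This list also passed without a count filter (−0.21), after GC correction (−0.20) and without DMSO replicate 3 (−0.16) or TRAP1 replicates 1 (−0.18) or 2 (−0.17). MYC fell by 0.60 ± 0.076 (adjusted p = 5.9e-09), and the list of MYC and ribosome biogenesis genes gave 13 rises and 12 falls among 36 [14 and 12] (median 0.03, adjusted p = 0.57). By edgeR, 2360 genes rose and 2145 fell, 556 of them by at least 2-fold.

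At 4 h the TRAP1 response was larger. CDKN1A reached 7760 ± 228 CPM against 161 ± 4.78 CPM with DMSO, a 48.2-fold rise (5.59 ± 0.058 (adjusted p = 7.6e-57)). TP53INP1 rose from 1.49 to 55.5 CPM (5.21 ± 0.34 (adjusted p = 3.6e-17)). GDF15 rose from 14.6 to 266 ± 21.9 CPM (4.18 ± 0.16 (adjusted p = 4.2e-24)). The remaining genes of the 10 largest rises were MAFA (4.92), FAM46C (3.90), ID3 (3.75), POU3F1 (3.73), BFSP1 (3.42), INSIG1 (3.40) and HIST2H2BE (3.30), where ID3 is a helix-loop-helix repressor and INSIG1 a sterol sensor of the endoplasmic reticulum. HAS2 fell to 1.17 ± 0.558 CPM from 42.7 ± 4.45 (−5.17 ± 0.31 (adjusted p = 3.0e-14)). Next came HCAR1 (−4.30), ALKBH4 (−4.17), B3GNT7 (−3.32), GIMAP6 (−3.22), RNF214 (−3.09), ZFP64 (−3.06), HEY1 (−2.96), FNTB (−2.83) and SH3TC1 (−2.83). FNTB did not pass with only the compared groups fitted (adjusted p = 0.12).

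The p53 target list at 4 h of TRAP1 gave 56 rises and 8 falls among 82 [58 and 8] (median 0.68, adjusted p = 1.3e-30). All 13 arrest genes rose (median 1.98, adjusted p = 1.4e-57). In the apoptosis branch, 11 of 17 rose and 1 fell [11 and 1] (median 0.48, adjusted p = 8.5e-08), with TNFRSF10D (2.97), TP53I3 (2.23) and BBC3 (2.74) among the rises. In the repair branch, 5 of 7 rose and 1 fell [6 and 1] (median 1.36, adjusted p = 2.6e-05). MDM2 now rose, by 0.94 ± 0.12 (adjusted p = 9.7e-10), and FAS stood at 0.41 ± 0.20 (adjusted p = 0.079). Without TRAP1 replicate 3, FAS passed at 0.56 (adjusted p = 0.030). G2/M genes repressed through p21 and the DREAM complex shifted down, with 5 rises and 25 falls among 36 [5 and 27] (median −0.38, adjusted p = 1.7e-07). The mitotic kinase genes PLK1 (−1.70), AURKA (−1.25) and BUB1B (−1.20) fell and the securin gene PTTG1 rose (0.85). Among G1/S and replication genes, 14 of 40 rose and 20 fell [14 and 21] (median −0.22, adjusted p = 0.37). PCNA, itself a p53 target, rose by 1.06 and E2F2 fell by 2.43. BET inhibitor-induced genes gave 16 rises among 17 and 0 falls [16 and 0] (median 1.77, adjusted p = 6.6e-36), with HEXIM1 (2.01), SERPINI1 (2.99), BRD2 (1.77) and SAT1 (2.15).

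Several other lists shifted up at 4 h of TRAP1. Those of cholesterol synthesis, unfolded protein and heat shock, immediate early and integrated stress response genes had also done so at 2 h. Cholesterol synthesis genes gave 21 rises and 1 fall among 25 [21 and 1] (median 0.61, adjusted p = 6.4e-22), with IDI1 (2.43) and FDFT1 (1.25). Unfolded protein and heat shock genes gave 21 rises and 2 falls among 25 [21 and 2] (median 0.72, adjusted p = 4.2e-26). Immediate early genes gave 23 rises and 5 falls among 33 [23 and 6] (median 1.04, adjusted p = 3.1e-13) and integrated stress response genes 17 rises and 4 falls among 23 [17 and 4] (median 0.78, adjusted p = 5.0e-09). NRF2 targets gave 16 rises and 1 fall among 22 [16 and 1] (median 0.63, adjusted p = 5.7e-09) and hypoxia and glycolysis genes 16 rises and 1 fall among 21 [16 and 1] (median 0.49, adjusted p = 2.1e-07). TGF-beta and YAP targets shifted up, with 10 rises and 2 falls among 20 [10 and 5] (median 0.26, adjusted p = 6.6e-05), among them ID3. Of pancreatic ductal and epithelial genes, 20 of 32 rose and 5 fell [22 and 5] (median 0.35, adjusted p = 3.2e-04), with KRT5 up (0.84) and the basal transcription factor gene TP63 down (−1.69). In BCL2-family genes, 5 of 19 rose and 7 fell [5 and 7] (median −0.21, adjusted p = 0.82). The proapoptotic BCL2L11 (2.13) and BBC3 (2.74) rose and the prosurvival BCL2L1 fell (−0.83). By edgeR, 3326 genes rose and 3674 fell, 1950 of them by at least 2-fold. Without TRAP1 replicate 1, the library that stood apart, 3137 rose and 3316 fell. The list medians were then 0.66 (p53 targets), −0.40 (G2/M), 1.73 (BET inhibitor-induced), 0.65 (cholesterol synthesis) and −0.11 (BCL2-family).

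**Figure D2:**
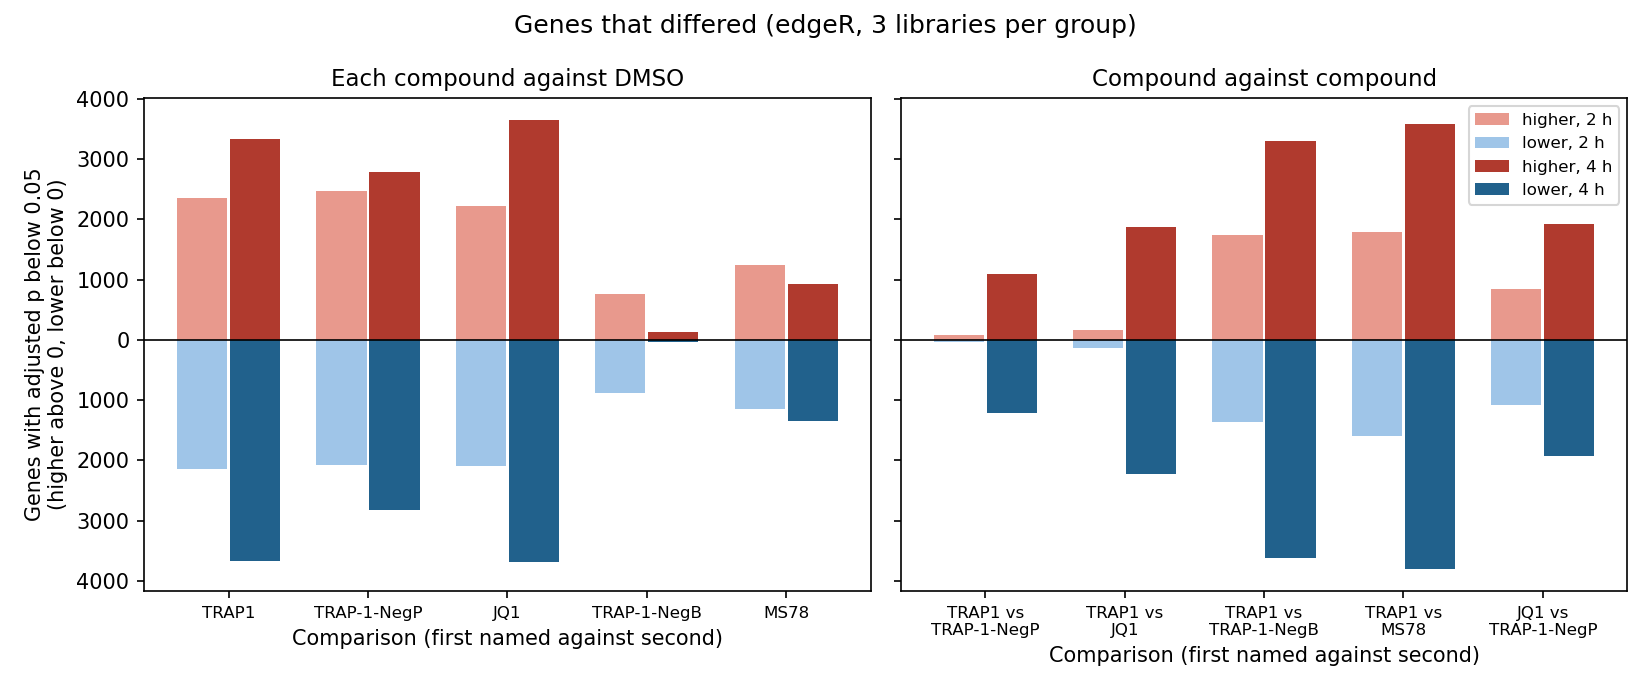
Number of genes higher (above 0) and lower (below 0) with an adjusted p under 0.05 in each of the 20 pair comparisons, at 2 and 4 h. TRAP1, TRAP-1-NegP and JQ1 against DMSO gave 4314 to 7326 genes, and TRAP-1-NegB against DMSO at 4 h gave 154.

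TRAP-1-NegP, a control compound of TRAP1, shared many of the changes but moved p53 targets far less. At 2 h its largest rises were VASN (2.59), FAM46C (2.57), INSIG1 (2.45), BAMBI (2.42) and TNFSF9 (2.31) and its largest falls HAS2 (−3.70), ALKBH4 (−2.29), HCAR1 (−2.12), DOK7 (−2.0) and PRICKLE1 (−1.88). CDKN1A rose by 0.86 ± 0.049 (adjusted p = 1.3e-20), while MDM2 fell by 0.65 ± 0.12 (adjusted p = 1.5e-05). By 4 h, INSIG1 had risen to 375 ± 17.8 CPM from 25 ± 1.82 (3.91 ± 0.081 (adjusted p = 2.8e-41)), with FAM46C (3.50), HIST2H2BE (3.22), BFSP1 (3.19) and TMED7-TICAM2 (3.14) next. The largest falls were HAS2 (−4.75), SH3TC1 (−2.93), B3GNT7 (−2.80), ALKBH4 (−2.56) and PRICKLE1 (−2.50). CDKN1A rose by 2.08 at that time, FAS fell by 0.80 (adjusted p = 0.0014) and MDM2 fell by 0.77 (adjusted p = 5.4e-07). TP53INP1, chosen here after its values were seen, stood at 0.37 (adjusted p = 0.46) and GDF15 at 0.31 (adjusted p = 0.13). GDF15 passed when no count filter was applied (0.30; adjusted p = 0.044).

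Of p53 targets with TRAP-1-NegP, 24 of 82 rose and 18 fell [26 and 19] at 2 h (median 0.10, adjusted p = 0.031) and 34 of 82 rose and 15 fell [34 and 15] at 4 h (median 0.23, adjusted p = 1.3e-06). The arrest branch gave 9 rises and 0 falls among 13 [9 and 0] at 4 h (median 0.66, adjusted p = 2.0e-15) with PLK3 (1.42) and SESN2 (1.58). BET inhibitor-induced genes gave 14 rises and 0 falls among 17 [14 and 1] (median 1.06, adjusted p = 7.4e-31) and 16 rises and 0 falls among 17 [16 and 0] (median 1.57, adjusted p = 1.2e-47). At 4 h, cholesterol synthesis genes gave 22 rises and 1 fall among 25 [22 and 1] (median 1.09, adjusted p = 9.4e-52). NF-kB genes gave 3 rises and 14 falls among 27 [3 and 14] (median −0.38, adjusted p = 0.014), with falls of IL1B (−1.14), LIF (−1.61) and BCL3 (−1.69) and a rise of SOD2 (0.84). In all, 2462 genes rose and 2080 fell at 2 h (edgeR), and 2781 and 2827 at 4 h, with 484 and 1257 at least 2-fold. The p53 list at 2 h did not pass without a count filter (0.06; adjusted p = 0.14).

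Direct comparison of TRAP1 with TRAP-1-NegP asks what TRAP1 did beyond this control, at the same dose and times. At 2 h the genes highest in TRAP1 were the p53 targets TP53INP1 (3.17 ± 0.33 (adjusted p = 3.6e-09)), CDKN1A (2.80 ± 0.051 (adjusted p = 4.5e-44)) and GDF15 (2.21 ± 0.16 (adjusted p = 1.7e-13)). They were followed by RGS16 (1.99) and POU3F1 (1.89). Those lowest in TRAP1 were ZNF579 (−0.79), INSIG1 (−0.70), KTI12 (−0.65), DDX28 (−0.63) and MAP1S (−0.61). The calls of ZNF579, KTI12 and MAP1S were lost without single libraries, each TRAP1 and TRAP-1-NegP library for 1 or more of them, at changes from −0.90 to −0.57. That of ZNF579 was also lost after GC correction (−0.64). DESeq2 gave no adjusted p for TP53INP1 and RGS16 at 2 h, with changes of 3.19 and 2.00. At 4 h TP53INP1 (4.84 ± 0.33 (adjusted p = 1.8e-15)), the neuronal transcription factor gene NHLH2 (4.25 ± 0.69 (adjusted p = 1.2e-05)), GDF15 (3.88 ± 0.16 (adjusted p = 3.0e-22)), CDKN1A (3.51 ± 0.052 (adjusted p = 1.2e-48)) and RGS16 (3.11) led the rises. The lowest were HJURP (−1.47), SLC29A2 (−1.41), ZNF518A (−1.38), ZNF367 (−1.38) and OVCA2 (−1.32), of which HJURP loads the centromeric histone. MDM2 was higher by 0.70 ± 0.12 (adjusted p = 1.5e-04) at 2 h and 1.72 ± 0.12 (adjusted p = 8.0e-17) at 4 h, and FAS by 1.21 (adjusted p = 1.1e-05) at 4 h.

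In the p53 list, 19 of 82 were higher and 0 lower [31 and 0] in TRAP1 than in TRAP-1-NegP at 2 h (median 0.17, adjusted p = 8.0e-50). By 4 h, 49 of 82 were higher and 2 lower [54 and 3] (median 0.43, adjusted p = 2.9e-64). The arrest branch gave 12 of 13 higher at 4 h (median 1.36, adjusted p = 2.6e-113). The apoptosis branch gave 10 higher and 1 lower of 17 [12 and 1] (median 0.54, adjusted p = 3.1e-15), with TP53I3 (2.14) and PHLDA3 (1.00). G2/M genes lay below, with 1 higher and 22 lower among 36 [2 and 28] (median −0.34, adjusted p = 1.0e-24), among them PLK1 (−1.08), MKI67 (−0.77), AURKA (−0.90) and CDCA8 (−0.74). So did G1/S genes, with 3 higher and 15 lower among 40 [3 and 17] (median −0.16, adjusted p = 7.4e-05). TGF-beta and YAP targets lay above, with 8 higher and 0 lower among 20 [9 and 1] (median 0.17, adjusted p = 1.5e-15), with NUAK2 (2.02) and ID3 (1.83). Cholesterol synthesis genes were lower in TRAP1 at 4 h, with 0 higher and 12 lower among 25 [1 and 15] (median −0.24, adjusted p = 3.8e-07). Inflammatory IL1B (1.93) and IL1A (1.57) were higher, in a list that gave 4 higher and 0 lower among 27 [7 and 0] (median 0.13, adjusted p = 1.5e-04).

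Genes that mark BET inhibition differed little between TRAP1 and TRAP-1-NegP. The difference in HEXIM1 was 0.17 ± 0.08 at 2 h (adjusted p = 0.42; 95% interval 0.01 to 0.33) and 0.39 (adjusted p = 2.5e-04) at 4 h. That in BRD2 was 0.10 (0.01 to 0.20; adjusted p = 0.14) and that in SERPINI1 0.06 (−0.51 to 0.63; adjusted p = 0.93) at 4 h. With only the compared groups fitted HEXIM1 passed at 2 h (adjusted p = 0.019), and BRD2 passed at 4 h by DESeq2 (0.11) and after GC correction (0.18). BET inhibitor-induced genes gave 5 higher and 0 lower among 17 [5 and 0] (median 0.06, adjusted p = 0.022). By edgeR, 79 genes were higher and 41 lower in TRAP1 at 2 h, and 1087 and 1213 at 4 h. The 2 h counts moved with the fit, to 450 and 662 with only the compared groups fitted, 138 and 95 by DESeq2 and 134 and 42 after GC correction. They were at most 58 and 22 without any 1 library. Leaving out TRAP1 replicate 3 gave 48 and 6. At 4 h, fitting only the compared groups gave 1122 and 764, and leaving out TRAP1 replicate 1 gave 846 and 862 with a p53 median of 0.47.

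**Figure D3:**
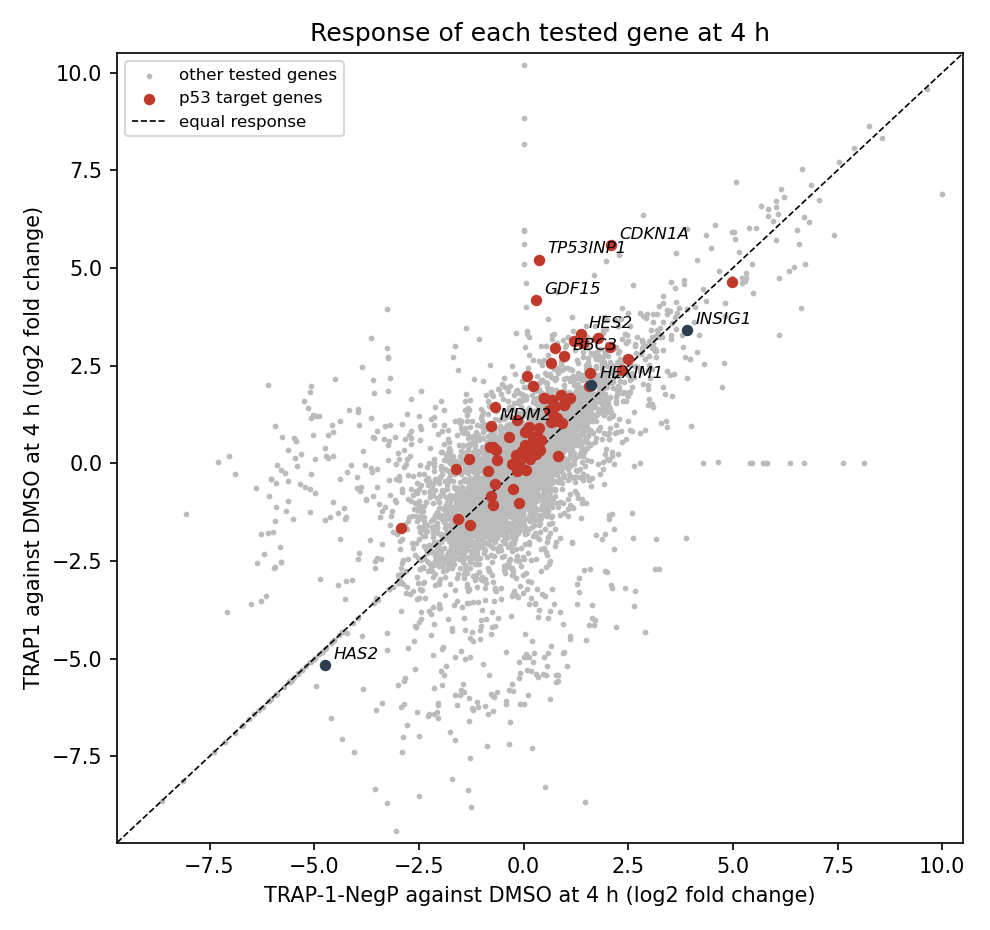
Log2 fold change against DMSO at 4 h of TRAP1 (y axis) and TRAP-1-NegP (x axis); each point is 1 of 14988 tested genes, with p53 target genes in red, and the line marks equal change. CDKN1A lies at 2.08 and 5.59, TP53INP1 and GDF15 lie far above the line, and HAS2 lies near it at −4.75 and −5.17.

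JQ1 against DMSO shows the response to a BET inhibitor in these cells. At 2 h the largest rises were FAM46C (3.38), EGR1 (3.21), BAMBI (2.84), CTGF (2.69) and VASN (2.67) and the largest falls HAS2 (−3.87), ALKBH4 (−3.54), FAM109B (−2.56), DOK7 (−2.49) and GIMAP8 (−2.14). At 4 h they were MAFA (5.20), TRIM36 (4.59), FAM46C (4.16), HIST2H2BE (3.59) and SERPINI1 (3.56) and HAS2 (−5.59), ALKBH4 (−5.04), ANKRD65 (−4.07), ZMYND8 (−3.50) and HCAR1 (−3.39). HEXIM1 rose by 1.14 ± 0.082 (adjusted p = 6.0e-17) at 2 h and 1.95 ± 0.083 (adjusted p = 7.7e-27) at 4 h, BRD2 by 1.09 and 1.78, and CDKN1A by 1.02 and 2.13. MYC fell, with changes of −0.75 (adjusted p = 1.4e-11) and −0.63 (adjusted p = 4.7e-10), and so did MDM2, with −0.59 (adjusted p = 6.6e-05) and −0.69 (adjusted p = 3.1e-06). GDF15 stood at −0.32 (adjusted p = 0.098) at 4 h, and passed without DMSO replicate 1 (−0.42), without a count filter (−0.35) and without the libraries that stood apart (−0.34).

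BET inhibitor-induced genes under JQ1 gave 15 rises and 1 fall among 17 [15 and 1] at 2 h (median 1.14, adjusted p = 4.8e-37) and 16 rises and 0 falls among 17 [16 and 0] at 4 h (median 1.78, adjusted p = 1.1e-36). BET proteins and pause-release factors gave 13 rises and 7 falls among 27 [13 and 7] at 4 h (median 0.28, adjusted p = 0.0088; without a count filter 0.18, adjusted p = 0.063), with the elongation factor genes ELL2 (1.19) and AFF4 (1.36) up and NELFA down (−1.62). For p53 targets, 22 of 82 rose and 16 fell [27 and 19] (median 0.09, adjusted p = 0.0035) and 37 of 82 rose and 16 fell [39 and 16] (median 0.28, adjusted p = 4.3e-05). FAS (−1.12) and PHLDA3 (−1.20) fell at 4 h while TNFRSF10D rose (2.72). Unfolded protein and heat shock genes gave 21 rises and 3 falls among 25 [21 and 3] at 4 h (median 0.83, adjusted p = 1.6e-22), and NF-kB genes 4 rises and 13 falls among 27 [4 and 13] (median −0.41, adjusted p = 0.024). MYC and ribosome biogenesis genes gave 8 rises and 18 falls among 36 [9 and 19] at 4 h (median −0.23, adjusted p = 0.017, and adjusted p = 0.057 with an estimated correlation). This list did not pass after GC correction (−0.23; adjusted p = 0.21). Prosurvival BCL2L1 fell by 1.5 ± 0.066 (adjusted p = 3.6e-26) and proapoptotic BCL2L11 rose by 2.52 ± 0.13 (adjusted p = 4.7e-24). The counts were 2225 higher and 2089 lower at 2 h (edgeR), and 3642 and 3684 at 4 h, 660 and 2133 of them at least 2-fold.

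TRAP1 and JQ1 parted over the same p53 targets. At 2 h the genes highest in TRAP1 were TP53INP1 (2.83), CDKN1A (2.64), GDF15 (2.58), ZBTB5 (1.68) and POU3F1 (1.46) and the lowest EGR1 (−0.90), SNX29 (−0.75), PPTC7 (−0.72), KLF7 (−0.69) and MYLIP (−0.67). At 4 h GDF15 was higher by 4.51 ± 0.16 (adjusted p = 5.4e-24) and CDKN1A by 3.46 ± 0.052 (adjusted p = 2.3e-48), beside NHLH2 (4.23), TP53INP1 (3.84) and NEURL2 (2.82). ZNF367 (−1.93), FNTB (−1.74), ATAD5 (−1.62), FBXO5 (−1.56) and E2F2 (−1.48) were the lowest. SNX29, PPTC7 and KLF7 lost their calls without single libraries (TRAP1 replicates 1, 2 or 3, JQ1 replicates 1 or 2), at −0.76 to −0.58, and SNX29 also after GC correction (−0.66). FNTB lost its call without TRAP1 replicates 1 or 2 or JQ1 replicate 2, at −1.62 to −1.12, and with only the compared groups fitted (adjusted p = 0.44). MDM2 was higher in TRAP1 by 0.64 (adjusted p = 4.2e-04) at 2 h and 1.63 (adjusted p = 3.3e-16) at 4 h, and FAS by 1.54 (adjusted p = 5.5e-08) at 4 h. HEXIM1 differed by 0.08 ± 0.08 (−0.08 to 0.24; adjusted p = 0.79) and 0.06 ± 0.079 (−0.09 to 0.22; adjusted p = 0.60), and BRD2 by −0.01 (−0.10 to 0.09; adjusted p = 0.93) at 4 h.

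Across the p53 list, 19 of 82 were higher and 0 lower [27 and 1] in TRAP1 than in JQ1 at 2 h (median 0.17, adjusted p = 1.2e-35). By 4 h, 46 of 82 were higher and 3 lower [52 and 3] (median 0.37, adjusted p = 2.1e-37). G2/M genes at 4 h gave 1 higher and 25 lower among 36 [1 and 26] (median −0.40, adjusted p = 3.7e-17), with MKI67 (−1.12), CENPF (−1.21) and TOP2A (−0.67). G1/S genes gave 4 higher and 19 lower among 40 [4 and 19] (median −0.20, adjusted p = 5.4e-04). Immediate early genes were lower in TRAP1 at 2 h, with 2 higher and 5 lower among 33 [3 and 10] (median −0.25, adjusted p = 1.1e-05). Cholesterol synthesis genes were higher at 4 h, with 13 higher and 1 lower among 25 [15 and 3] (median 0.23, adjusted p = 9.4e-11). NF-kB genes gave 6 higher and 2 lower among 27 [6 and 3] (median 0.22, adjusted p = 3.1e-04), with IL1B (2.74), LIF (2.05) and IL1A (1.72). By edgeR, 165 genes were higher and 133 lower at 2 h, and 1877 and 2236 at 4 h. At 2 h, fitting only the compared groups gave 510 and 526, DESeq2 263 and 251, and leaving out JQ1 replicate 1 gave 78 and 46. At 4 h, GC correction gave 1879 and 1479.

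JQ1 and TRAP-1-NegP were also set against each other. At 2 h C4orf29 (1.07), CCRN4L (1.03) and MYLIP (1.02) were highest in JQ1 and LDLRAD2 (−1.39), PLD4 (−1.34) and ZNF579 (−1.17) lowest. At 4 h the extremes were KCNQ1OT1 (1.71), CEP85L (1.39) and KBTBD8 (1.35) and INSIG1 (−1.64), RPSAP52 (−1.54) and ZMYND8 (−1.23). LDLRAD2 lost its call without every library but TRAP-1-NegP replicate 2, at −1.58 to −1.05, and after GC correction (−1.29). Cholesterol synthesis genes were lower in JQ1 at 4 h, with 1 higher and 19 lower among 25 [1 and 20] (median −0.47, adjusted p = 1.2e-36). BET inhibitor-induced genes were higher, with 7 higher and 0 lower among 17 [10 and 0] (median 0.33, adjusted p = 9.6e-04). For p53 targets, 14 of 82 were higher and 5 lower [15 and 7] at 2 h (median 0.05, adjusted p = 0.37) and 18 of 82 were higher and 13 lower [21 and 14] at 4 h (median 0.06, adjusted p = 0.50). CDKN1A differed by 0.05 ± 0.048 (−0.04 to 0.15; adjusted p = 0.47) at 4 h, and by 0.26 (adjusted p = 7.5e-09) after GC correction. By edgeR, 847 genes were higher and 1088 lower at 2 h, and 1926 and 1926 at 4 h. Fitting only the compared groups gave 1695 higher at 2 h, GC correction 764 and 652 at 2 h and 1249 higher at 4 h, and leaving out JQ1 replicate 2 gave 583 lower at 2 h.

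TRAP-1-NegB, the other control compound that carries the name of TRAP1, moved few genes by much. The cytochrome P450 genes CYP1A1 and CYP1B1, classical targets of the aryl hydrocarbon receptor, led them. CYP1A1 rose from 1.65 ± 0.214 to 22.6 ± 1.20 CPM at 2 h (3.77 ± 0.27 (adjusted p = 4.6e-16)) and from 0.957 to 32.0 ± 0.792 CPM at 4 h (5.04 ± 0.29 (adjusted p = 7.8e-20)). CYP1B1 rose by 3.31 ± 0.15 (adjusted p = 1.2e-18) and 3.81 ± 0.16 (adjusted p = 5.5e-20). TIPARP, another target of that receptor, rose at 2 h (1.46), with SHISA2 (1.88) and PTGS2 (1.40). The largest falls were TRAPPC5 (−1.36), SMIM22 (−1.09), RPS19BP1 (−1.08), NDUFB7 (−1.05) and CRB3 (−1.02). At 4 h INSIG1 (1.72), VIPR1 (1.56) and SERPINB2 (1.25) followed the P450 genes, and SNHG19 (−1.11), ABCA1 (−0.73), FUT4 (−0.59), EGLN3 (−0.57) and HDDC3 (−0.56) were the largest falls. ABCA1 exports cholesterol. The calls of ABCA1, FUT4, EGLN3 and HDDC3 were lost without single libraries, each of the 6 for 1 or more of them, at −0.74 to −0.47. That of HDDC3 was also lost without a count filter (adjusted p = 0.088) and on length-scaled counts (adjusted p = 0.059). CDKN1A rose by 0.48 ± 0.049 (adjusted p = 7.7e-11) at 2 h and 0.69 ± 0.049 (adjusted p = 2.9e-16) at 4 h, and HEXIM1 stood at 0.14 (−0.03 to 0.31; adjusted p = 0.60) at 4 h.

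Cholesterol synthesis genes were the list that TRAP-1-NegB moved most clearly at 4 h, with 13 rises and 0 falls among 25 [18 and 0] (median 0.33, adjusted p = 8.7e-61), with HMGCS1 (1.06) and IDI1 (0.80). Integrated stress response genes gave 5 rises and 0 falls among 23 [6 and 0] (median 0.12, adjusted p = 2.0e-10), the rises including the amino acid transporter gene SLC7A5 (0.89). Of p53 targets, 11 of 82 rose and 3 fell [12 and 5] at 2 h (median 0.04, adjusted p = 0.12) and 5 of 82 rose and 1 fell [6 and 1] at 4 h (median 0.05, adjusted p = 0.013). The 2 h list passed without TRAP-1-NegB replicate 2 (0.07) and the 4 h list did not without DMSO replicate 1 (0.04) or with only the compared groups fitted (0.06). BET inhibitor-induced genes at 4 h gave 1 rise and 0 falls among 17 [1 and 1] (median 0.08, adjusted p = 0.13). Inflammatory genes at 2 h gave 6 rises and 0 falls among 27 [6 and 0] (median 0.13, adjusted p = 0.0024). By edgeR, 761 genes rose and 880 fell at 2 h, and 124 and 30 at 4 h, with 32 and 15 at least 2-fold. Fitting only the compared groups gave 1362 and 1333 at 2 h. At 4 h GC correction gave 235 and 73, leaving out DMSO replicate 2 gave 76 rises, and leaving out DMSO replicate 3 gave 13 falls.

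TRAP1 was also set against TRAP-1-NegB at both times. At 2 h FAM46C (3.37), CDKN1A (3.18), POU3F1 (2.75) and ID3 (2.71) were the highest with a usable fold, and HAS2 (−4.14), CYP1B1 (−4.09), CYP1A1 (−3.31), ARTN (−2.38) and ALKBH4 (−2.37) the lowest. At 4 h MAFA (5.42), CDKN1A (4.90), TP53INP1 (4.40), ID3 (4.25) and GDF15 (3.94) and HAS2 (−5.53), CYP1B1 (−5.33), HCAR1 (−4.23), CYP1A1 (−4.17) and ALKBH4 (−4.08) were the extremes. The histone gene HIST2H4A was also named at 2 h, but it was listed at 0 in all 3 TRAP-1-NegB libraries and shares its sequence with a near-identical copy, so its reads are uncertain and no fold is given. Of p53 targets, 34 of 82 were higher and 7 lower [37 and 7] at 2 h (median 0.24, adjusted p = 1.0e-18) and 55 of 82 were higher and 9 lower [57 and 9] at 4 h (median 0.63, adjusted p = 1.9e-29). Of BET inhibitor-induced genes, 16 of 17 were higher and 0 lower [16 and 0] at 4 h (median 1.67, adjusted p = 5.6e-36). The counts were 1739 higher and 1368 lower at 2 h (edgeR), where fitting only the compared groups gave 2277 lower, no count filter gave 1342 and 1590, and leaving out TRAP-1-NegB replicate 2 gave 1149 higher. At 4 h they were 3295 and 3620.

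MS78 likewise raised CYP1A1 and CYP1B1. CYP1A1 rose by 2.77 ± 0.26 (adjusted p = 2.5e-11) at 2 h and by 4.79 ± 0.29 (adjusted p = 3.8e-19) at 4 h, to 26.8 ± 3.82 CPM, and CYP1B1 by 2.33 and 3.87. At 2 h the AP-1 and stress factor genes FOSB (1.71) and ATF3 (1.36) and the collagen gene COL18A1 (1.23) followed. The largest falls were TMED8 (−1.5), ZBED6 (−1.28), IL8 (−1.27), LMBRD2 (−1.21) and FUT11 (−1.15). IL8 encodes a neutrophil chemokine. COL18A1 (0.78) and IL8 (−0.88) did not pass without MS78 replicate 1, the library that stood apart, nor did IL8 without DMSO replicate 1 (−1.14). With only the compared groups fitted, COL18A1, IL8 and LMBRD2 did not pass (adjusted p = 0.067, 0.083 and 0.067). At 4 h the sterol genes INSIG1 (2.54), HMGCS1 (1.73) and MSMO1 (1.56) followed, and CFD (−1.08), PGF (−1.04), DUSP2 (−1.02), TRAPPC5 (−1.01) and ZNF688 (−0.94) were the largest falls. CDKN1A stood at −0.11 (−0.21 to −0.01; adjusted p = 0.13) at 2 h and 0.01 (−0.09 to 0.11; adjusted p = 0.93) at 4 h, and HEXIM1 at 0.04 (−0.12 to 0.21; adjusted p = 0.79) at 4 h. Without MS78 replicate 1, CDKN1A fell at 2 h (−0.17; adjusted p = 0.0031), and GC correction gave −0.16 at 2 h and 0.21 at 4 h, both passing. MDM2 rose at 4 h by 0.34 ± 0.12 (adjusted p = 0.036). This call was lost after GC correction (0.17), on length-scaled counts (0.33), and without DMSO replicate 2 (0.30), MS78 replicate 1 (0.25) or MS78 replicate 3 (0.35).

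Cholesterol synthesis genes rose under MS78, with 7 rises and 1 fall among 25 [7 and 1] at 2 h (median 0.07, adjusted p = 0.0012) and 18 rises and 0 falls among 25 [19 and 0] at 4 h (median 0.66, adjusted p = 1.7e-74). Of p53 targets, 10 of 82 rose and 8 fell [11 and 8] (median −0.04, adjusted p = 0.80) and 11 of 82 rose and 11 fell [12 and 11] (median 0.03, adjusted p = 0.53). G2/M genes shifted up at 4 h, with 17 rises and 2 falls among 36 [20 and 4] (median 0.18, adjusted p = 3.0e-05), with NUSAP1 (0.48), TTK (0.58) and CENPF (0.46). MYC and ribosome biogenesis genes shifted up at 2 h, with 14 rises and 2 falls among 36 [19 and 3] (median 0.15, adjusted p = 1.7e-05), with NCL (0.54) and NOP58 (0.71). By edgeR, 1244 genes rose and 1146 fell at 2 h, and 934 and 1356 at 4 h, 70 and 52 of them at least 2-fold. The 2 h counts were 141 and 178 with only the compared groups fitted and 716 falls without DMSO replicate 2. At 4 h GC correction gave 451 and 541, leaving out both libraries that stood apart 1789 and 1606, leaving out MS78 replicate 1 gave 574 rises and leaving out DMSO replicate 3 gave 700 falls.

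TRAP1 exceeded MS78 at both times in p53 targets, with 39 higher and 9 lower among 82 [46 and 9] at 2 h (median 0.33, adjusted p = 1.6e-24) and 57 higher and 12 lower among 82 [57 and 13] at 4 h (median 0.65, adjusted p = 4.6e-27). It did so in BET inhibitor-induced genes, with 16 higher and 0 lower among 17 [16 and 0] at 4 h (median 1.69, adjusted p = 2.7e-31). The largest differences at 2 h were CDKN1A (3.77), FAM46C (3.08), TP53INP1 (3.01), POU3F1 (2.88) and RGS16 (2.88) on the high side and HAS2 (−3.81), CYP1B1 (−3.10), ALKBH4 (−2.68), CYP1A1 (−2.31) and ARTN (−1.98) on the low side. At 4 h they were CDKN1A (5.58), MAFA (4.58), ID3 (4.54) and GDF15 (4.27) and HAS2 (−5.74), CYP1B1 (−5.39), HCAR1 (−4.39), CYP1A1 (−3.92) and ALKBH4 (−3.63). HIST2H4A was again named but listed at 0 in all 3 MS78 libraries, and no fold is given. G2/M genes lay lower in TRAP1 at 4 h, with 3 higher and 28 lower among 36 [3 and 28] (median −0.58, adjusted p = 2.8e-12). By edgeR, 1796 genes were higher and 1592 lower at 2 h, 621 and 981 with only the compared groups fitted, and 3587 and 3801 at 4 h.

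**Figure D4:**
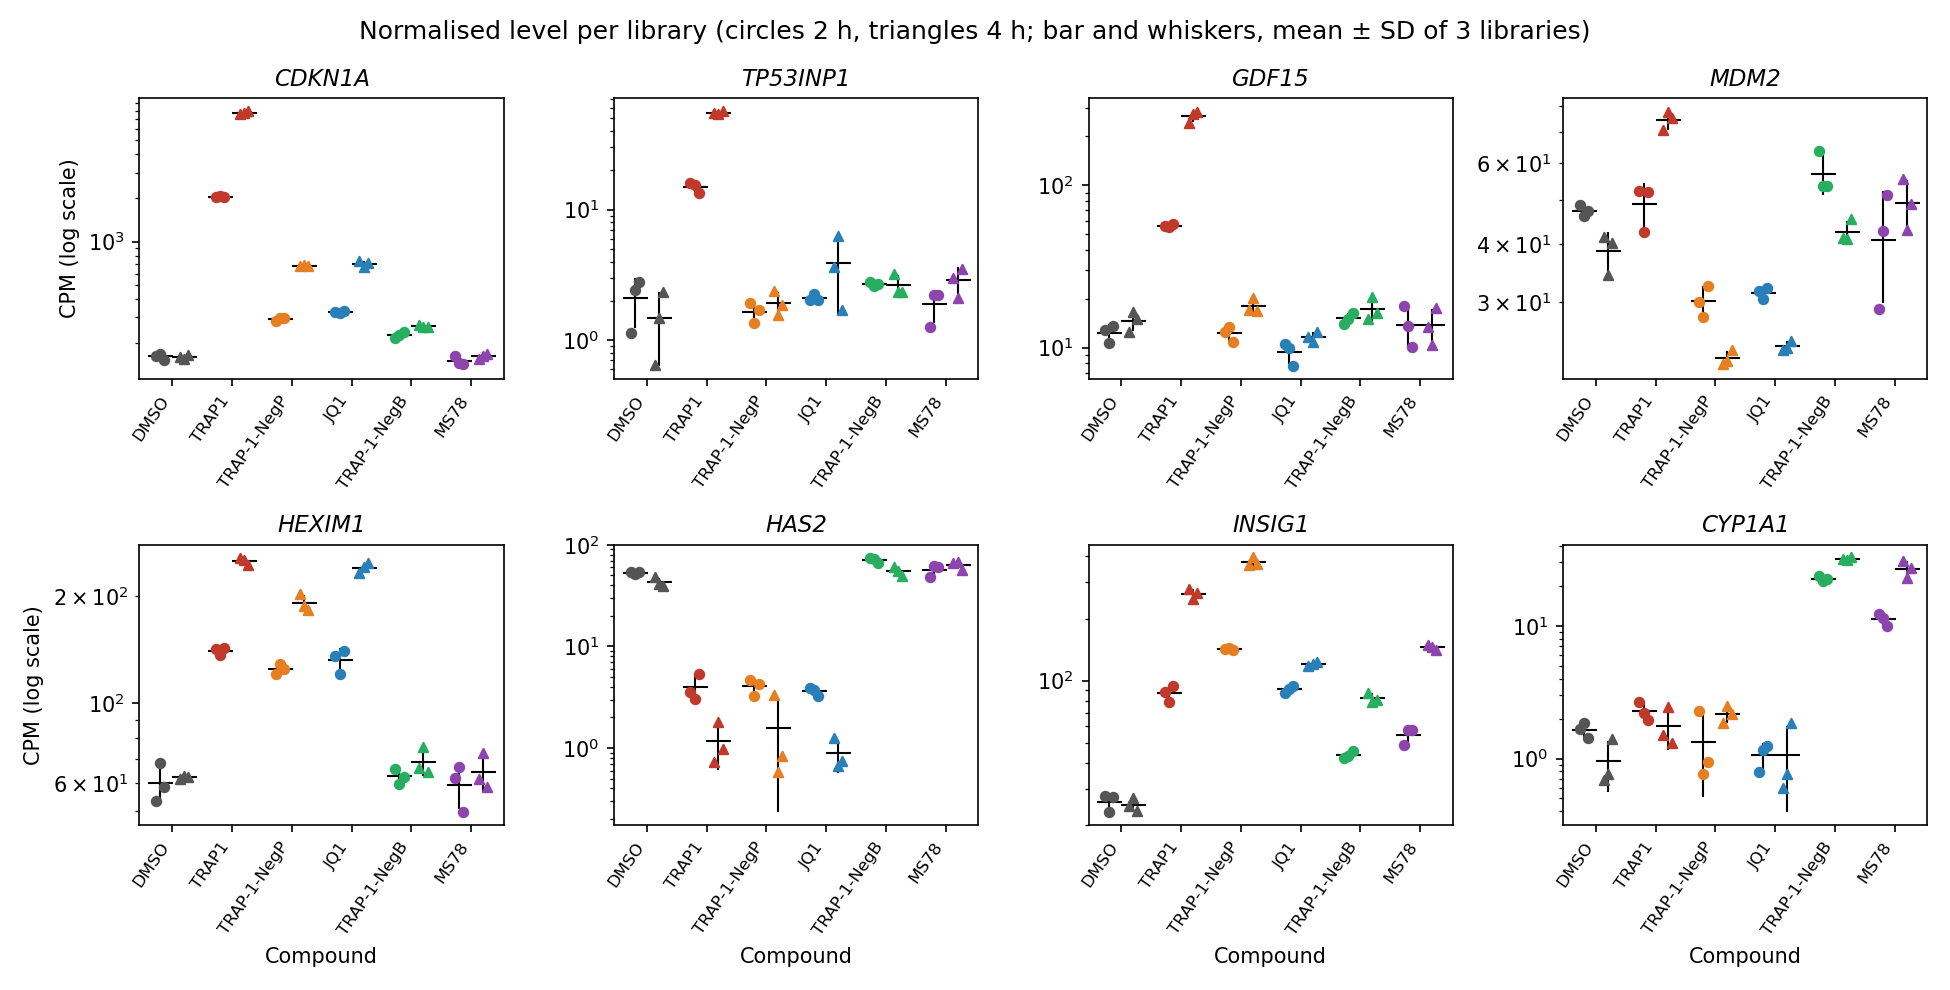
Level of 8 genes (CPM, log axis) in the 12 groups; points are the 3 libraries of a group and bars the mean ± SD. CDKN1A stood at 7760 CPM with TRAP1 at 4 h against 679 with TRAP-1-NegP and 161 with DMSO, and CYP1A1 stood at 32.0 CPM with TRAP-1-NegB and 26.8 with MS78.

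Across the 5 compounds, the gene lists fell into a few profiles. BET inhibitor-induced genes had medians of 1.77, 1.57 and 1.78 at 4 h under TRAP1, TRAP-1-NegP and JQ1, against 0.08 (adjusted p = 0.13) under TRAP-1-NegB and 0.05 (adjusted p = 0.37; after GC correction 0.16, adjusted p = 0.041) under MS78. Cholesterol synthesis genes rose under all 5 compounds at 4 h, with medians from 0.33 (TRAP-1-NegB) to 1.09 (TRAP-1-NegP). The p53 list had its highest 4 h median under TRAP1, 0.68, then JQ1 at 0.28 and TRAP-1-NegP at 0.23. Over the 20 pair comparisons, 209 of 460 list tests passed with the preset correlation and 186 of these also with an estimated correlation. With the preset correlation no call had a median of the sign opposite to its test. With the estimated correlation 1 did: NF-kB genes in TRAP-1-NegB against DMSO at 4 h (adjusted p = 0.049) had a median of −0.05 and an upward test. Apart from p53 targets, adjusting over a list alone moved its count of rises by at most 2 genes in 414 of 440 cases and its count of falls in 423.

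**Figure D5:**
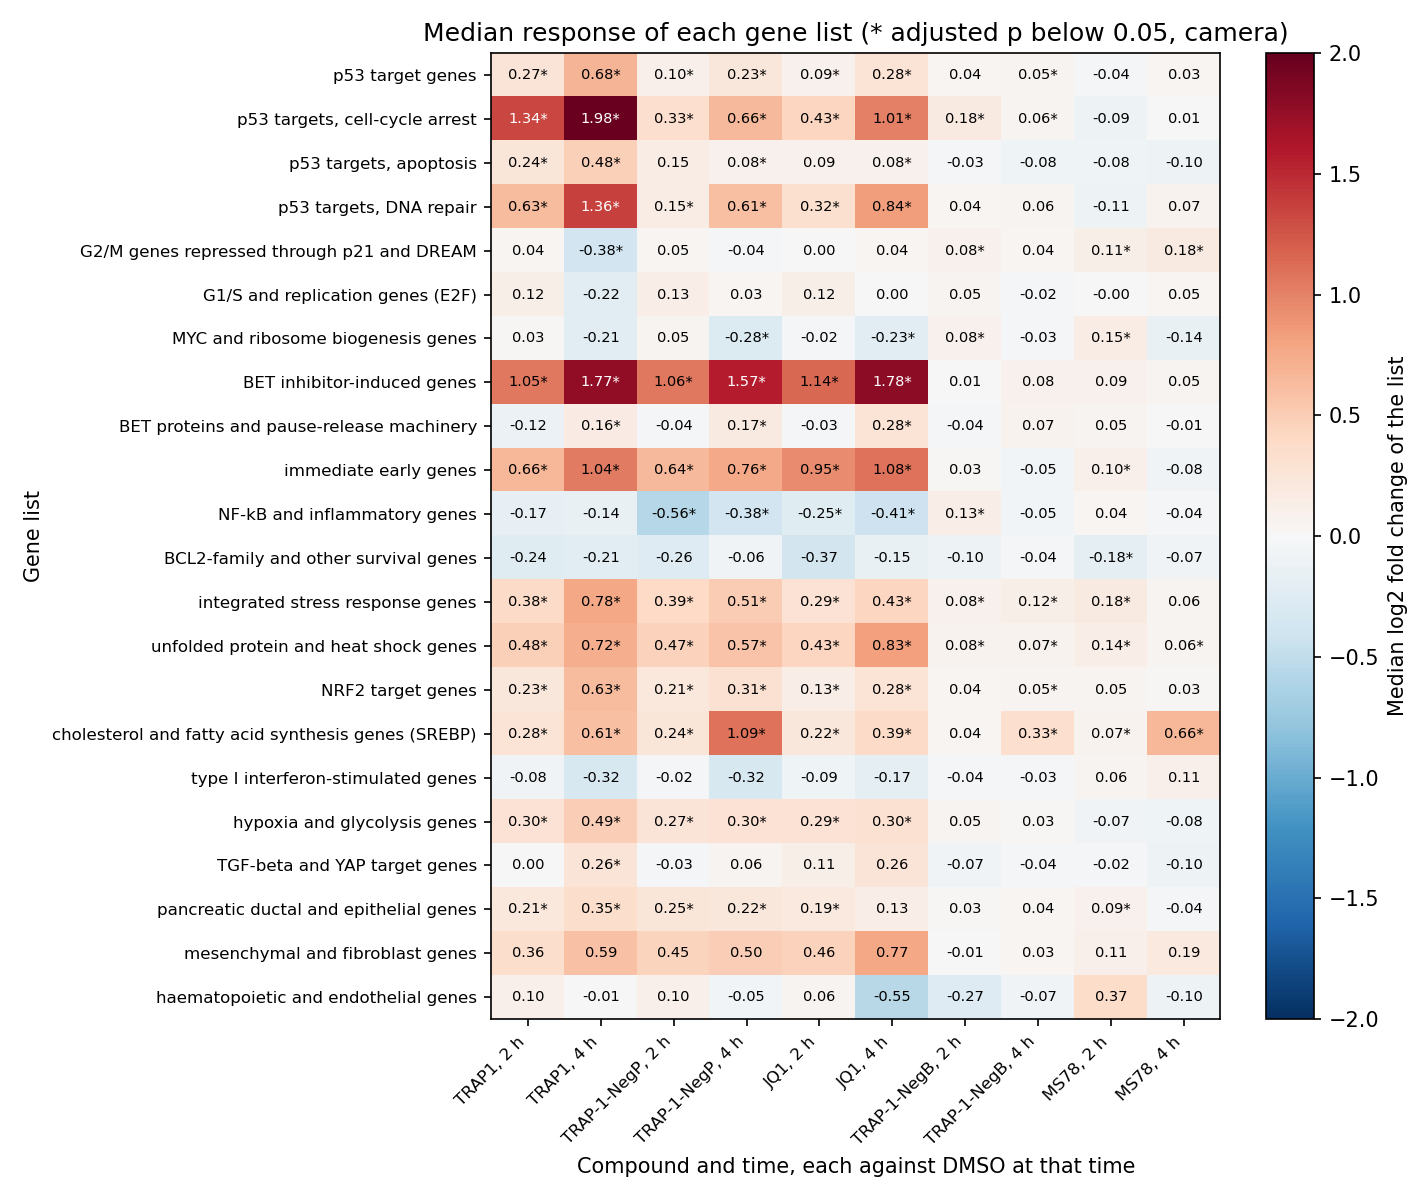
Median log2 fold change against DMSO of each of 22 tested gene lists for the 5 compounds at 2 and 4 h, on a colour scale centred at 0; a star marks an adjusted p under 0.05. The p53 list reads 0.68 for TRAP1 at 4 h, and the BET inhibitor-induced list reads 1.77 for TRAP1, 1.57 for TRAP-1-NegP and 1.78 for JQ1.

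How far the responses of TRAP1 and each other compound overlapped was measured over the 14988 tested genes, which are not independent replicates. At 4 h, 2325 genes rose and 2352 fell under both TRAP1 and TRAP-1-NegP, where independent calls would give 617 and 693, and 41 moved in opposite directions. For JQ1 the counts were 2437 and 2654, against 808 and 903, with 149 opposite. For MS78 they were 455 and 444, against 207 and 332, with 560 opposite. For TRAP-1-NegB they were 75 and 10, against 27.5 and 7.35, with 39 opposite. The number of opposite moves under independent calls was not worked out, so the opposite counts alone show no opposition to TRAP1. The correlation of log2 changes with TRAP1 at 4 h was 0.649 (TRAP-1-NegP), 0.680 (JQ1), 0.276 (TRAP-1-NegB) and 0.214 (MS78). Simulated libraries without any effect that shared their controls gave 0.505, 0.50, 0.509 and 0.499. Covariances exceeded the simulated ones by 0.63, 0.77, 0.07 and 0.02. At 2 h the correlations were 0.687, 0.724, 0.489 and 0.449, against simulated 0.481, 0.498, 0.504 and 0.491, with covariance differences of 0.32, 0.35, 0.09 and 0.11. All responses used the same 3 DMSO libraries per time, so part of any excess overlap can come from the controls.

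The TRAP1 effect was also compared with the sum of the TRAP-1-NegB and TRAP-1-NegP effects on the log2 scale. CDKN1A exceeded the sum by 2.32 ± 0.069 (adjusted p = 4.4e-33) at 2 h and 2.82 ± 0.069 (adjusted p = 2.4e-37) at 4 h, GDF15 by 1.91 and 3.63 ± 0.22 (adjusted p = 4.3e-16), and MDM2 by 1.58 ± 0.17 (adjusted p = 3.1e-10) at 4 h. Of p53 targets, 17 of 82 lay above the sum and 0 below at 2 h [22 and 0] (median 0.22, adjusted p = 5.4e-13), and 35 above and 1 below at 4 h [42 and 2] (median 0.48, adjusted p = 2.4e-42). Cholesterol synthesis genes lay below the sum at 4 h, 17 of 25 below and 0 above [20 and 0] (median −0.66, adjusted p = 2.4e-41), with INSIG1, chosen after its values were seen, at −2.23 ± 0.10 (adjusted p = 4.4e-24). HEXIM1 departed by 0.25 (0.02 to 0.48; adjusted p = 0.21) at 4 h. By edgeR, 750 genes departed from the sum at 2 h and 1044 at 4 h. At 2 h fitting only the compared groups gave 1844, leaving out both libraries that stood apart 1377 and GC correction 1140.

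DMSO libraries of 4 h were also compared with those of 2 h. From 2 to 4 h, G2/M genes rose, with 20 rises and 0 falls among 36 [21 and 0] (median 0.28, adjusted p = 3.3e-16), and G1/S genes shifted down, with 4 rises and 15 falls among 40 [5 and 18] (median −0.18, adjusted p = 0.0021). CDKN1A stood at −0.01 (−0.11 to 0.09; adjusted p = 0.95) and MYC rose by 0.27 ± 0.075 (adjusted p = 0.0058). After GC correction CDKN1A fell (−0.24; adjusted p = 4.6e-07) and MYC did not pass (0.11; adjusted p = 0.36). MYC also did not pass without DMSO 2 h replicate 3 (0.23; adjusted p = 0.060). By edgeR, 1704 genes rose and 1417 fell, 3121 in all, and 1794 in all, 57.5%, after GC correction. These changes followed GC content (Spearman rho 0.63) across the more highly expressed genes with a GC content, which are not independent replicates.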

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

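The GC correction, its test on the MS78 calls at 4 h, the tests of a scaled TRAP-1-NegP response and of a sum of both control responses, and the regroupings for the p53 list median of the time differences and of the departure from that sum, were chosen after the results were seen; the other tests were chosen before.

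Effects that differed between 4 and 2 h were singled out by a test of the difference itself. For TRAP1, 3295 genes differed (edgeR), TRAP-1-NegP gave 3476, JQ1 3900, MS78 2282 and TRAP-1-NegB 372. Of the preset panel, the TRAP1 effect differed for CDKN1A by 1.93 ± 0.069 (adjusted p = 3.3e-29), GDF15 by 2.00 ± 0.21 (adjusted p = 2.1e-09), MDM2 by 0.90 ± 0.16 (adjusted p = 3.6e-05), BTG2 by 0.50 ± 0.14 (adjusted p = 0.0072), which did not pass without DMSO 4 h replicate 3 (0.39; adjusted p = 0.055), HEXIM1 by 0.78 ± 0.12 (adjusted p = 6.2e-07) and BRD2 by 0.69 ± 0.067 (adjusted p = 2.3e-11). The p53 list had a median difference of 0.42 for TRAP1, with 38 of 82 genes higher and 2 lower at 4 h [42 and 3] (adjusted p = 4.3e-19), of 0.16 for TRAP-1-NegP (adjusted p = 0.0020) and of 0.14 for JQ1 (adjusted p = 0.0042). Of 100 regroupings within each time, the real one included, 1 gave as many genes as the real one for TRAP1, TRAP-1-NegP, JQ1 and MS78. With only the compared groups fitted, TRAP1 gave 3573 against 1966 for the highest other. TRAP-1-NegP gave 4229 against 1234, JQ1 4596 against 2963 and MS78 833 against 23. For TRAP-1-NegB 3 regroupings gave as many (646 against 695). Regrouping mixed compound with DMSO libraries and so also removed the compound effect at each time. These counts therefore cannot tell a difference between times from chance. The p53 list median was as large in 10 of 100 regroupings for TRAP1 (0.42 against 0.70 for the highest other), in 10 for TRAP-1-NegP (0.17 against 0.23) and in 10 for JQ1 (0.13 against 0.28). All 10 of each kept the real grouping at 4 h and so held its effect, and this count says nothing about chance for the list.

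TRAP-1-NegB and MS78 changed many genes by little: the called genes had a median absolute change of 0.38 for TRAP-1-NegB at 2 h and of 0.37 and 0.35 for MS78 at 2 and 4 h. Correcting for GC content and length changed the count of calls at 2 h to 115% for TRAP-1-NegB (1893 against 1641) and to 111% for MS78 (2659 against 2390). These totals include new calls. Of the first calls, 1304 and 1991 stayed in the same direction. Across the more highly expressed genes with a GC content, which are not independent replicates, the 2 h changes followed GC content. Spearman rho was −0.29 (TRAP-1-NegB) and 0.24 (MS78). The larger part of the first calls thus stayed, which argues against such a trend as the source of those that did. For the rest it remains a candidate. At 4 h the correction changed the count of MS78 calls to 43.3% (992 against 2290), with 717 of the first calls shared. There the changes of the more highly expressed genes followed GC content with a Spearman rho of −0.69, so GC bias is a candidate source of the larger part of these calls. The correction also lowered recovery of simulated 1.5-fold changes (74% to 66%). Of the 3067 genes called for either compound at 2 h, 31.1% (954) differed between the compounds, but these genes were chosen for a call in 1 of them, so the share excludes nothing. Over all genes 475 differed, and 964 were called for both compounds in the same direction and 0 in opposite directions, so a shift of the shared DMSO libraries stays open beside an effect of both compounds.

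The TRAP1 response at 4 h rested on a group with 1 library apart. Leaving out that library, replicate 1, kept 92.2% of the count of calls (6453 of 7000) and 96.9% of the p53 list median (0.66 against 0.68), so neither was carried by it. What set the library apart was not tested; no biological explanation was tested, since the labels give it no difference from its replicates.

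The p53 targets above TRAP-1-NegP could come from a common scaling of the same response. The list's median TRAP1 effect lay 0.20 at 2 h and 0.44 at 4 h above the mean of 10000 lists matched on TRAP-1-NegP effect and expression, and above the highest of them (0.27 against 0.24, and 0.68 against 0.44), which argues against scaling as the whole source, although the draws do not allow for correlation among the list's genes. The sum of the TRAP-1-NegB and TRAP-1-NegP effects fell short by a median of 0.22 at 2 h (adjusted p = 5.4e-13) and 0.48 at 4 h (adjusted p = 2.4e-42) by the list test, which argues against simple addition on the log2 scale. A compound-specific action of TRAP1 on these genes is a hypothesis that stays open, found and tested on the same data. For the departure from the sum, 1 of 100 regroupings, the real one included, gave as many genes as the real one, at 2 h (1844 against 23) and at 4 h (972 against 53). Regrouping mixed the libraries of all groups in the contrast and so removed each compound's own effect too. These counts therefore cannot tell a departure from the sum from chance. The list median was as large in 16 at 2 h (0.21 against 0.29) and in 24 at 4 h (0.50 against 0.82). That median followed the means of the real groups across regroupings (r 0.958 and 0.987) and so says nothing about chance.

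With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Every other split mixed libraries of both groups, so any real effect widened the spread within groups and lowered the calls. A part of the real effect also stayed in the list median of such a split. The values below are therefore given as a description and cannot tell an effect from chance. Fitting only the compared groups, the real split and the highest of the other splits gave, against DMSO at 2 h, 5991 and 0 genes (TRAP1), 2695 and 1 (TRAP-1-NegB), 5864 and 0 (TRAP-1-NegP), 5565 and 0 (JQ1) and 319 and 2 (MS78). At 4 h they gave 6230 and 0, 225 and 3, 5635 and 0, 7473 and 0, and 2990 and 1, in the same order. TRAP1 against TRAP-1-NegB, TRAP-1-NegP, JQ1 and MS78 gave 4259 and 1, 1112 and 2, 1036 and 3, and 1602 and 1 at 2 h, and 6202 and 0, 1886 and 1, 3560 and 1, and 6721 and 0 at 4 h. JQ1 against TRAP-1-NegP gave 3318 and 0 at 2 h and 4256 and 1 at 4 h, and DMSO at 4 against 2 h gave 3976 and 1. The p53 list median, real and highest other, was 0.26 and 0.14 for TRAP1 against DMSO at 2 h and 0.68 and 0.29 at 4 h; against TRAP-1-NegB 0.20 and 0.13, and 0.62 and 0.28; against TRAP-1-NegP 0.17 and 0.11, and 0.43 and 0.21; against JQ1 0.17 and 0.091, and 0.39 and 0.18; and against MS78 0.32 and 0.17, and 0.64 and 0.25.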

How the results depend on the processing

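The GC and length correction and the fit without both libraries that stood apart were chosen after the data were seen; the other alternatives were planned. All were run, but the DESeq2 Wald test gave a value for 633 of 644 list results, the fit of only the compared groups for 2512 and the stricter filter for 2514 of the 2523 single-gene results. Of the list results, those on time differences, DMSO over time and the departure from the sum included, between 592 (GC correction) and 641 (replicate block) kept their direction and side of the threshold under each alternative fitted once, and 1 reversed. Of 2523 single-gene results, 2293 kept theirs under GC correction, 27 reversed and 188 lost the call; of 15216 results with 1 library left out, 1098 lost the call. All 8 shared-response correlations kept their sign and stayed within a spread taken from the fits with 1 library left out, but that spread was wide. Without DMSO 2 h replicate 1 the TRAP-1-NegB correlation at 2 h rose from 0.489 to 0.609 and that of MS78 from 0.449 to 0.575. Without TRAP1 4 h replicate 3 that of TRAP-1-NegP at 4 h fell from 0.649 to 0.542. The simulations were not repeated without a library. Replicate numbers paired the libraries weakly at most (mean correlation of deviations 0.0034 for equal and −0.0017 for different numbers). Of 36 libraries, 19 were closest to their own number, above the share that chance would give, so a weak pairing is not excluded. The replicate block moved no count by over 1.5 times. Below, pairs of counts are genes higher and lower, and the cause of each move was not tested unless fewer libraries were fitted.

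GC trends were not confined to TRAP-1-NegB and MS78 at 2 h, MS78 at 4 h and DMSO over time. Across the more highly expressed genes, Spearman rho was −0.42 for TRAP1 against TRAP-1-NegP at 2 h and 0.37 for TRAP1 against JQ1 at 4 h. It was −0.52 for JQ1 against TRAP-1-NegP and −0.31 for TRAP-1-NegB against DMSO at 4 h. For TRAP1 against DMSO it was −0.06 at 2 h and −0.09 at 4 h. Under GC correction, ductal and epithelial genes under MS78 at 4 h reversed to 0.055, SOD2 in TRAP1 against JQ1 at 4 h to 0.17 and ISG15 in JQ1 against TRAP-1-NegP at 2 h to 0.062. Counts moved by over 1.5 times were, with GC correction, DMSO over time 1794, JQ1 against TRAP-1-NegP 652 lower at 2 h and 1249 higher at 4 h, MS78 451 and 541 at 4 h with 985 differing between times, TRAP-1-NegB 235 and 73 at 4 h with 605 differing between times, TRAP1 against JQ1 1479 lower at 4 h, TRAP1 against TRAP-1-NegP 134 higher at 2 h (42 lower), and departure from the sum 1140 at 2 h. The DESeq2 Wald test gave 50 lower for TRAP-1-NegB at 4 h, 263 and 251 for TRAP1 against JQ1 and 138 and 95 against TRAP-1-NegP at 2 h; no count filter gave 69 lower, 250 higher, and 139 and 104 for the same comparisons. Without both libraries that stood apart, TRAP-1-NegB gave 1316 higher at 2 h (1005 lower), 294 and 84 at 4 h and 715 between times, MS78 1789 higher at 4 h and 1299 between times, JQ1 against TRAP-1-NegP 1316 higher at 2 h, TRAP1 against JQ1 385 and 308 and against TRAP-1-NegP 217 and 246 at 2 h, and departure from the sum 1377 at 2 h. With only the compared groups fitted, JQ1 against TRAP-1-NegP gave 1695 higher at 2 h; MS78 141 and 178 at 2 h, 1428 higher at 4 h and 833 between times; TRAP-1-NegB 1362 and 1333 at 2 h, 59 lower at 4 h and 646 between times; TRAP1 against JQ1 510 and 526, against MS78 621 and 981, against TRAP-1-NegB 2277 lower and against TRAP-1-NegP 450 and 662 at 2 h, and against TRAP-1-NegP 764 lower at 4 h; departure from the sum 1844 at 2 h.

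Leaving out each library in turn, with the pair left in a group assumed to vary like the other groups, the counts that moved ranged as follows. JQ1 against TRAP-1-NegP at 2 h ranged from 534 (without TRAP-1-NegP replicate 1) to 732 higher and from 583 (JQ1 replicate 2) to 991 lower; MS78 at 2 h from 716 to 1390 lower, at 4 h from 574 (MS78 replicate 1) to 1327 higher (DMSO replicate 1) and 700 (DMSO replicate 3) to 1224 lower, and between times from 1133 to 3400 (MS78 2 h replicates 1 and 3); TRAP-1-NegB at 2 h from 493 (its replicate 2) to 625 lower, at 4 h from 76 to 126 higher and 13 to 32 lower, and between times from 246 to 331; TRAP1 against JQ1 at 2 h from 78 to 151 higher and 46 to 131 lower (JQ1 replicates 1 and 3); TRAP1 against TRAP-1-NegB at 2 h from 1149 to 1329 higher; and TRAP1 against TRAP-1-NegP at 2 h from 48 to 58 higher and 6 to 22 lower.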

Other observations

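The tests in this part were planned except for the choice of CYP1A1 and CYP1B1, and no explanation was tested.

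CYP1A1 and CYP1B1 did not move alike under the 5 compounds. CYP1B1 rose with TRAP-1-NegB and MS78 but fell with TRAP1 (−0.78 ± 0.16 (adjusted p = 2.7e-04) at 2 h and −1.52 at 4 h), and stood at −1.03 and −1.39 under TRAP-1-NegP and −1.16 and −1.83 under JQ1. CYP1A1 stood at 0.46 (adjusted p = 0.24) at 2 h and 0.88 (adjusted p = 0.022) at 4 h under TRAP1, at −0.32 (adjusted p = 0.50) and 1.18 (adjusted p = 0.0023) under TRAP-1-NegP and at −0.62 (adjusted p = 0.14) and 0.17 (adjusted p = 0.73) under JQ1, at 2 and 4 h. The 4 h call under TRAP1 was lost with only the compared groups fitted (adjusted p = 0.30) and without DMSO replicate 1 (0.67), DMSO replicate 2 (0.73) or TRAP1 replicate 2 (0.55). That under TRAP-1-NegP at 4 h was lost with only the compared groups fitted (adjusted p = 0.096), and at 2 h CYP1A1 passed downward without TRAP-1-NegP replicate 1 (−0.93; adjusted p = 0.043). Apart from TRAP-1-NegB and MS78, these pairs of gene and compound were chosen after their values were seen.

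Interferon-stimulated genes moved both ways under TRAP1 at 4 h: 8 of 30 rose and 13 fell [9 and 15] (median −0.32, adjusted p = 0.82), with IFIT2 at 1.49 and ISG15 at 1.01 against XAF1 at −1.86 and IRF9 at −1.07. Among markers of mesenchymal and fibroblast cells, 7 of 15 rose and 1 fell [8 and 1] (median 0.59, adjusted p = 0.15), with SNAI1 at 3.59, and among those of haematopoietic and endothelial cells 1 of 10 rose and 2 fell [1 and 2] (median −0.01, adjusted p = 0.82). Without TRAP1 replicate 1, the library that stood apart, the median of the last list was −0.81 (adjusted p = 0.80). TRAP1 against MS78 placed hypoxia and glycolysis genes higher at 4 h, with 17 higher and 1 lower among 21 [17 and 1] (median 0.57, adjusted p = 1.5e-08).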
